A study of Homo sapiens with 12 samples.

How the data were processed

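The data are 12 Affymetrix expression arrays of cultured primary human endothelial cells, 3 each from umbilical vein (HUVEC), saphenous vein (HSaVEC), aorta (HAoEC) and coronary artery (HCoEC). The cells came from 3 commercial suppliers, with HSaVEC and HAoEC from the same supplier. Vessel and source of the cells were therefore not separated by the design. Only HAoEC against HSaVEC was free of a difference in supplier, with donor and lot not named. Per the labels, all cells were grown to confluence in the same microvascular endothelial medium, RNA quality was checked on a Bioanalyzer, and biotin-labelled cRNA was hybridised to the arrays. The deposited table holds log2 expression values per probe set, with the unit read from the values themselves. The summarisation and normalization that the authors used to make these log2 values are not given in the sources used here.

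The deposited table has 33297 probe sets of a whole-transcript gene array. Of these, 19460 had 1 gene symbol in the annotation of the platform, 1754 had several and 12083 were not listed. Only probe sets with 1 symbol were used. Of the 19460 probe sets, 19429 were matched by gene identifier to a RefSeq gene table of assembly GRCh38.p14, used for names and chromosomes, and 0 symbols changed. Because the cells came from donors, 24 probe sets of XIST, TSIX and Y-linked genes were removed. Where a gene had more than 1 probe set (768 genes), the one with the highest mean over the 12 arrays was kept, which gave 18394 genes with a value. A gene was tested if its value exceeded the 25th percentile of gene probe sets of an array on at least 3 arrays. That left 14409 genes and set aside 3985. The filter level was between 4.86 and 5.64 on the 12 arrays. It is a percentile and not a measured background, and differences against values under it have an uncertain size.

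Array medians over all probe sets ran from 5.73 to 5.80 for the 8 arrays numbered 1 or 2 and from 6.27 to 6.36 for the 4 arrays numbered 3, so the deposited values had not all been brought to 1 distribution. No 2 arrays held identical values, and 0 columns of the table were left unmapped. An array has no read depth, so the number of arrays, 3 per vessel, limits the precision. The labels call the samples biological replicates but name no donor, lot or culture date, so the p-values measure the spread between these arrays, whatever its source.

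Differences were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes in a single fit of all 12 arrays with 1 mean per vessel, and p-values (2-sided) were adjusted by the Benjamini-Hochberg method over the 14409 genes, with a threshold of 0.05. The comparisons were the mean of the 2 arteries against the mean of the 2 veins, the 2 arteries against each other, the 2 veins against each other, and the 4 pairs of an artery with a vein. The 2 other ways of pairing the 4 vessels were tested beside the arterial and venous pairing, because a contrast of vessel means does not include the spread between vessels of 1 kind. A gene was called set apart in a vessel when it was called in the same direction against each of the other 3 vessels.

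The replicate numbers are shared by the 4 vessels in the labels, which do not say what a number stands for. The arrays' deviations from their vessel means were therefore correlated over genes. The 18 pairs of arrays of different vessels with the same number had correlations (across genes, which are not independent replicates) from 0.337 to 0.815, and pairs with different numbers ran from -0.733 to 0.642. For 8 of the 12 arrays the best match in another vessel had the same number. The numbers come from the sample titles, and that they pair the arrays was read from the data. The pairing set number 3 against numbers 1 and 2: with only numbers 1 and 2, same-number pairs ran from -0.377 to 0.293. The fit without the number remained the primary one, as fixed before the data were examined, and values from the fit with array number as a block are printed beside it where a count of genes or the call of a named gene or list changed.

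Gene lists were fixed before the data were examined: arterial, venous, lymphatic and pan-endothelial markers, Notch pathway, markers of smooth muscle and pericytes, fibroblasts, blood cells and mesothelium or epithelium, cell cycle, inflammatory adhesion and cytokine genes, interferon response, shear stress response, haemostasis and fibrinolysis, basement membrane and extracellular matrix, TGF-beta and BMP pathway, HOX genes, other regional transcription factors, axon guidance, hypoxia and glycolysis, and cholesterol biosynthesis. Each was tested with camera at its preset correlation, with camera at an estimated correlation, and with fry, adjusted over the 21 lists of a comparison. The fry test asks whether a list moves on balance in 1 direction, and its mixed form whether it changes in either direction. Members were also adjusted over the list alone. Of the 504 genes listed, 420 were tested, 37 fell below the filter, 7 were only in probe sets with several symbols and 40 were not analysed here.

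Named genes followed a rule fixed in advance. For arteries against veins these were genes past the threshold with the same sign in all 4 pairs and no overlap between the 6 arterial and 6 venous arrays, up to 12 in each direction. For 2 vessels they were genes past the threshold with no overlap between 3 and 3 arrays, up to 12 in each direction, a separation that chance alone gives to 10% of genes. For a vessel set apart, up to 5 higher and 3 lower genes were named, and from each list up to 4 called members plus any member of the arterial and venous marker lists. The rule was applied also to the fit with array number as a block, with the overlap read within each number, and that extension was chosen after the data were seen. Other genes named in the text were chosen after their values were seen and are said to be so. HLA genes, genes often deleted or duplicated in people, antisense and non-coding symbols were not named.

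The tests were checked on simulated arrays built from the measured gene means, residual spreads and number effects of the 14409 genes, with normally distributed noise and 200 genes changed by known amounts. The simulated number effects were additive, as the blocked fit assumes, and noise was drawn independently for each gene. Both arteries were given the same change, and so were both veins, so no added spread between the arteries or between the veins was simulated. The shares below therefore do not show how far calls for arteries against veins hold across vessels. For arteries against veins the fit without the number found 38.8% of genes changed by a fold of 2 and 87.9% of those changed by a fold of 4, and the fit with the block found 94.0% and 98.5%. Unchanged genes called were 0 in the fit without the number and 12 with the block, the latter 6.45% of its calls. For HSaVEC against HUVEC the fit without the number found 11.9% at a fold of 2 and 57.6% at a fold of 4, and the fit with the block 79.1% and 98.5%. For HCoEC against HAoEC these shares were 16.4% and 69.7% without the number and 80.6% and 100% with the block.

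The alternatives tried were no filter and a filter at the 50th percentile, quantile normalization, median centring, a trended robust prior, array weights, the mean of all probe sets of a gene, a test against a fold of 1.2, an unmoderated statistic, each array left out in turn, only the 6 arrays compared, arteries against veins ignoring vessel, and vessel as a random block. After seeing the data, fits without the 4 arrays numbered 3, with number 3 against 1 and 2 as a block, with the block and quantile normalization together, and with vessel as a random block beside the number were added, and the alternatives were repeated within the blocked fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.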

Results

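Gene expression was measured on 12 arrays of primary human endothelial cells, which line blood vessels. There were 3 arrays, called biological replicates in the labels and numbered 1 to 3, for each of 4 vessels of origin: umbilical vein (HUVEC), saphenous vein (HSaVEC), aorta (HAoEC) and coronary artery (HCoEC). All cells were grown in the same medium, and 14409 genes were tested. The series sets venous against arterial cells, and the questions addressed here are how the arteries differed from the veins, the coronary from the aortic cells, and the saphenous from the umbilical cells. Levels and differences are log2 values, and the number of arrays limits the precision.

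The arrays numbered 3 stood apart from those numbered 1 and 2 in all 4 vessels. Their median level over all probe sets ran from 6.27 to 6.36, against 5.73 to 5.80 on the other 8 arrays. Number explained 68.3% of the variance over genes beside vessel, and vessel explained 16.9%. The first principal component, with 67.0% of the variance, parted the arrays numbered 3 from the rest. Each comparison is therefore given from the fit with vessel alone and, where a call or count changed, from a fit with array number as a block. Differences within each number are given beside them. Genes with such values were named only if the compared arrays did not overlap, with the block within each number. Their shared sign across numbers is therefore no added support.

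**Figure D1:**
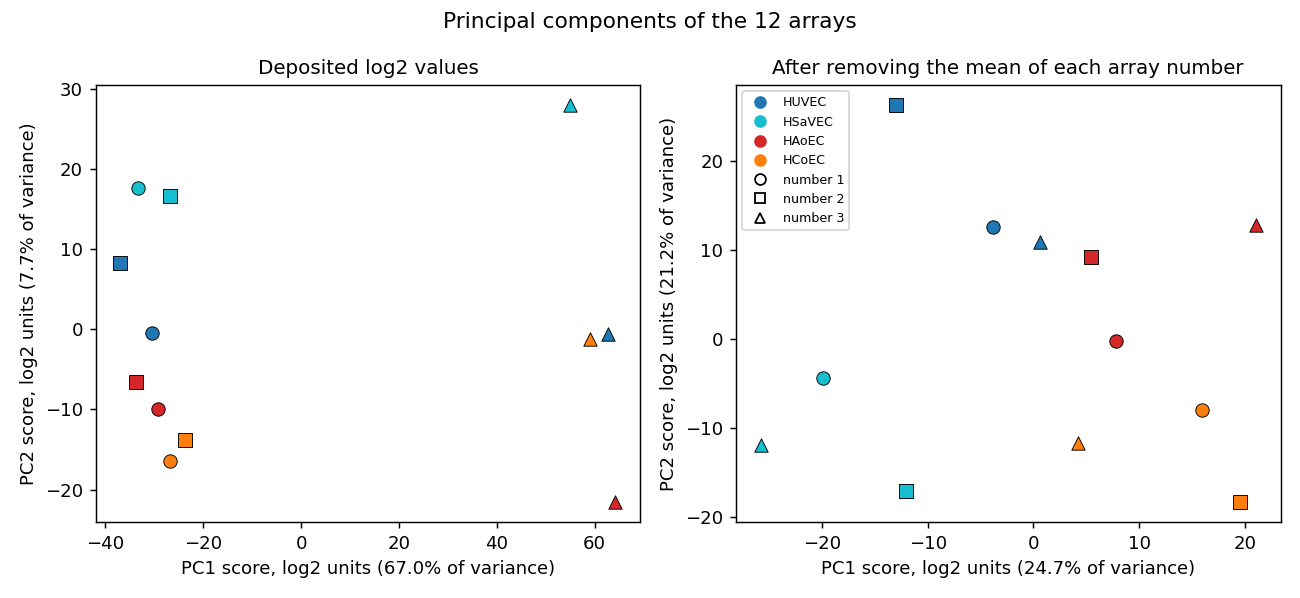
Principal components of the 12 arrays over tested genes, as deposited (first component 67.0%, second 7.68% of the variance) and after the mean of each array number was removed (24.7% and 21.2%); axes are component scores, colour gives the vessel and shape the array number. As deposited, the 4 arrays numbered 3 separate from the other 8 along the first component.

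Arterial cells had more of the laminin alpha 2 chain gene LAMA2, and venous cells more of the tight junction gene CLDN11. LAMA2 was 5.91-fold higher in the arteries (log2 difference 2.56, SE 0.20, n = 6 and 6 arrays; limma, Benjamini-Hochberg adjusted p = 0.000496), with means of 5.08 in HUVEC, 5.40 in HSaVEC and 7.42 in HCoEC. CLDN11 was 24.9-fold lower in the arteries (-4.64, SE 0.35, limma, Benjamini-Hochberg adjusted p = 0.000496), from 11.72 ± 0.88 (SD, n = 3) in HUVEC and 12.27 ± 0.56 in HSaVEC to 7.32 ± 0.66 in HAoEC and 7.39 ± 0.57 in HCoEC. The other genes higher in arteries were the organic anion transporter SLCO3A1 (1.54, SE 0.20) and the homeobox gene MEIS2 (0.88, SE 0.13). Lower in arteries were PLAC8 (-2.49, SE 0.34), the endothelin receptor EDNRB (-2.47, SE 0.34), FAM174B (-2.44, SE 0.29), the imprinted gene NNAT (-2.38, SE 0.29) and ALDH1A2 (-2.30, SE 0.29), whose enzyme makes retinoic acid. Also lower were POPDC1 (-1.65, SE 0.22), the endothelial sialomucin EMCN (-1.62, SE 0.21) and PROX1 (-1.48, SE 0.22), a regulator of lymphatic identity. No arterial array overlapped a venous one for these 12 genes. PLAC8 and EDNRB lay at or under the filter level on all 6 arterial arrays, so the size of their differences is uncertain. LAMA2 lay there on 2 HUVEC arrays and 1 HSaVEC array, and ALDH1A2 on 2 HCoEC arrays. PROX1 lay there on 1 HUVEC, 1 HAoEC and 2 HCoEC arrays. The size of these differences is uncertain too.

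In all, limma with Benjamini-Hochberg adjustment called 13 of 14409 genes, 3 higher and 10 lower in arteries, and 391 had an unadjusted p under 0.05. The 13th, AGMO (-2.26), had overlapping arrays and was named after its value was seen. AGMO lay at or under the filter level on 2 HUVEC, 3 HAoEC and 3 HCoEC arrays, so the size of its difference is uncertain. All 13 had the same sign in all 4 pairs of an artery with a vein, and were also called with number as a block. Of the genes named by the rule, which leaves out AGMO, 4 kept the call and 8 lost it with vessel as a random block beside number. With 2 groups ignoring vessel, 5 kept it and 7 lost it. Within numbers 1, 2 and 3 LAMA2 differed by 2.82, 2.65 and 2.23, and CLDN11 by -4.15, -4.34 and -5.42. A contrast of 2 arteries with 2 veins does not measure the spread between vessels of 1 kind, and each vessel's cells had a single commercial source. The count ran from 2 to 19 when 1 array was left out.

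**Figure D2:**
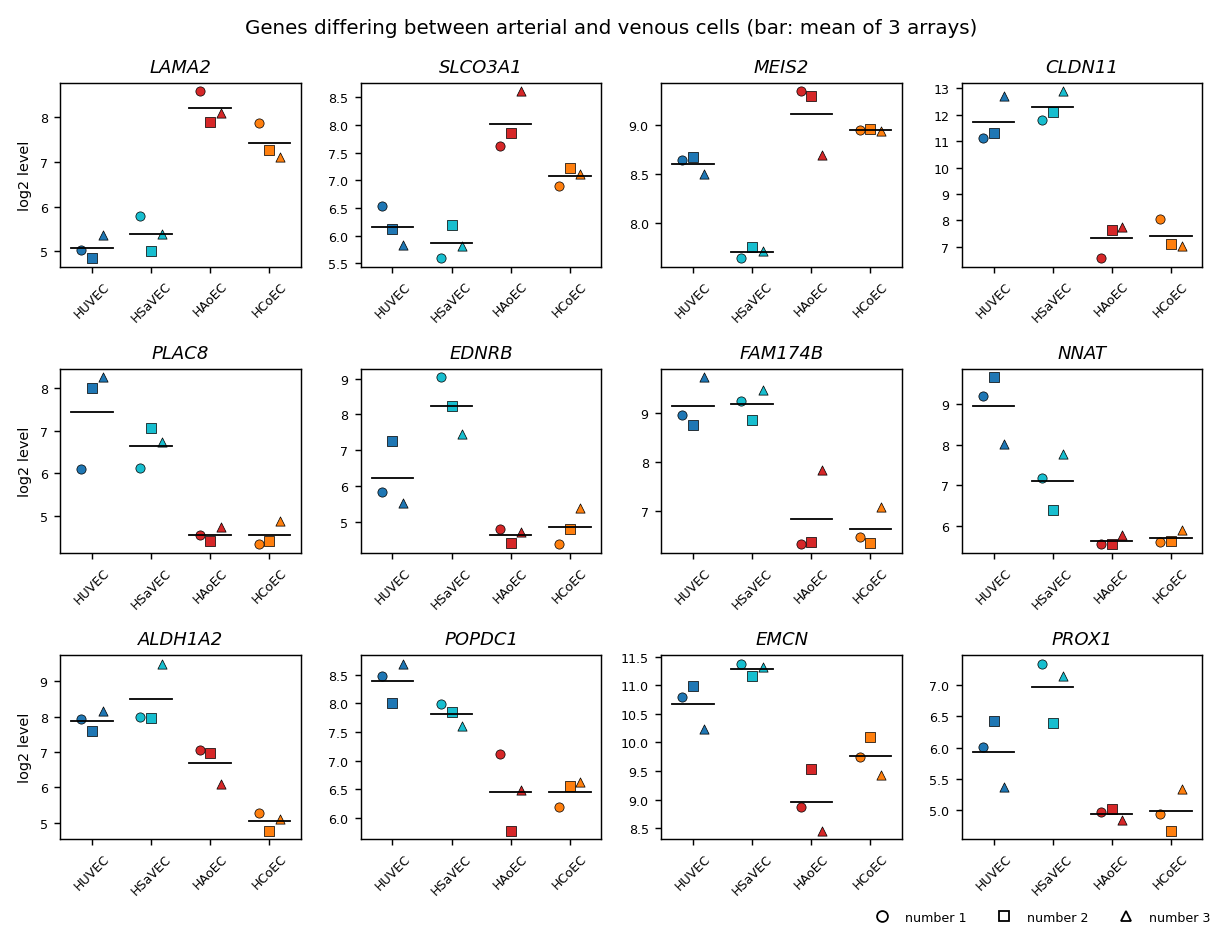
Log2 level (y axis) on each array of the 12 genes named for arteries against veins, by vessel of origin; points are arrays and bars are means of 3. CLDN11 has means of 11.72 and 12.27 in the veins and 7.32 and 7.39 in the arteries.

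With array number as a block, the count rose to 103 genes, 38 higher and 65 lower in arteries. HEY2, a transcriptional repressor induced by Notch, was 8.43-fold higher in arteries (SE 0.55; limma, Benjamini-Hochberg adjusted p = 0.0469 with the block and 0.296 without it). The Wnt antagonist DKK2 was 5.85-fold higher (2.55, SE 0.46), and SLIT2, which encodes a ligand of ROBO receptors, 4.01-fold higher (SE 0.24). ANTXR1 (1.64), DAW1 (1.38), the tensin gene TNS3, POU4F1, TSPAN2 (1.17), PLEKHA2 (1.15) and TSHZ3 (1.04) were higher too. The hyaluronan receptor LYVE1 was 9.26-fold lower in arteries (-3.21, SE 0.58; limma, Benjamini-Hochberg adjusted p = 0.0474 with the block and 0.110 without it). Lower as well were the homeobox gene MEOX2 (-2.80), the cytokine TNFSF15, the adenylate kinase AK5 (-2.04), the sestrin SESN3 (-1.95) and the adhesion receptor ADGRG6 (-1.80). DKK2 lay at or under the filter level on 2 HUVEC and 3 HSaVEC arrays, and AK5 on 3 HAoEC and 2 HCoEC arrays. HEY2 lay there on 2 HUVEC arrays, so the size of these differences is uncertain. Within numbers 1, 2 and 3 HEY2 differed by 2.72, 3.79 and 2.71, and LYVE1 by -1.99, -3.97 and -3.68. Of the 103 genes, 96 had the same sign in all 4 pairs, and 18 also differed between the veins. SLIT2 was among these, with a mean of 9.08 in HUVEC, 6.33 in HSaVEC, 9.90 in HAoEC and 9.52 in HCoEC. The count of 103 ran from 33 to 100 when 1 array was left out, and fell to 4 with vessel as a random block beside number.

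Arterial marker genes had a higher mean in the arterial cells, and venous and lymphatic marker genes a lower one, but fibroblast markers had a higher mean in the arterial cells too (0.73). The 27 tested arterial markers had a mean difference of 0.60 and a median of 0.30, the 16 venous markers -0.41 and -0.19, and the 11 lymphatic markers -0.55 and -0.16. In numbers 1, 2 and 3 the mean was 0.61, 0.59 and 0.60 for arterial markers, -0.48, -0.28 and -0.47 for venous markers, and -0.31, -0.62 and -0.73 for lymphatic markers. With camera at the preset correlation the adjusted p was 2.33e-13, 2.24e-07 and 7.22e-07 for arterial, venous and lymphatic markers. In the same order, the adjusted p was 0.0268, 0.0302 and 0.0302 with an estimated correlation, and 0.24, 0.256 and 0.24 with an estimated correlation and number as a block. With number as a block camera still called them at the preset correlation (adjusted p = 5.70e-06, 0.000664 and 0.000664). Over the 21 lists with the block, fry called 1 list moving in 1 direction, the lymphatic one (adjusted p = 0.0385), and 11 changing in either direction. The arterial and venous lists were not called in 1 direction with the block (adjusted p = 0.0725 for both), and none of the 3 was without it (adjusted p = 0.0593 for each). Over all genes 0 arterial markers, 1 venous (EMCN) and 1 lymphatic (PROX1) were called, and 3, 3 and 4 with the block. Adjusted over the list alone, 7 arterial, 3 venous and 4 lymphatic markers were called, and 9, 5 and 4 with the block. Those 9 were HEY2, DKK2, TSPAN2, the gap junction gene GJA5 (7.99-fold), the chemokine CXCL12, SEMA3G (0.74), ALDH1A3 (0.66), NOTCH4 (0.52) and SOX17 (0.42). The venous and lymphatic members called with the block and adjusted over the list alone were ADGRG6, EMCN, FLT4 (-1.51), CPE (-1.36), FLRT2 (-0.55), LYVE1, PROX1 and TFF3 (-0.87), with FLT4 in both lists.

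**Figure D3:**
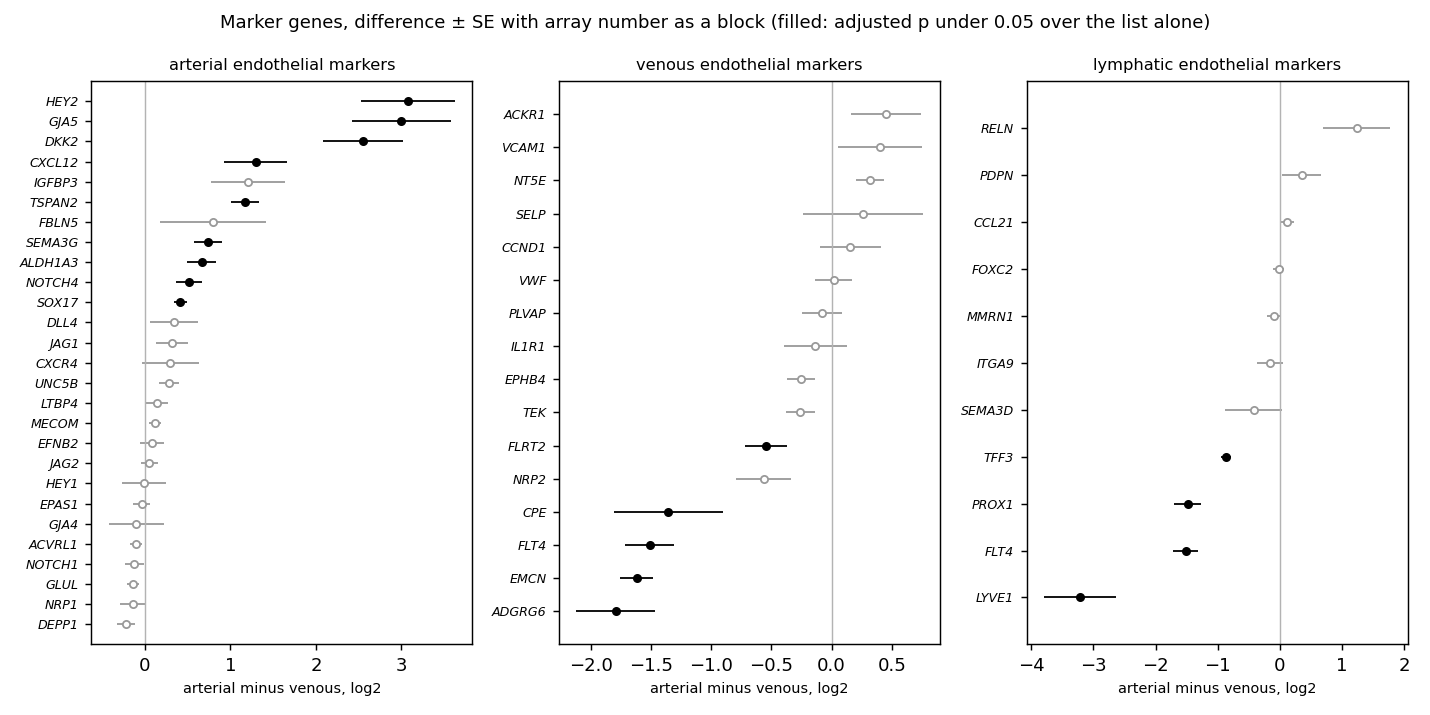
Arterial minus venous log2 difference (x axis) of each tested arterial, venous and lymphatic marker, with the standard error from the fit with array number as a block; filled symbols have an adjusted p under 0.05 over the list alone. The list means are 0.60, -0.41 and -0.55.

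Among lists of transcription factors, HOX genes had a mean of -0.20 and a median of 0.0034 between arteries and veins, which differ in sign. Of 39 HOX genes listed 23 were tested, with HOXA2 the only one of the HOXA cluster. HOXD8 (-0.67), HOXD9 (-0.52) and HOXD10 (-0.99) were called lower with number as a block and none without it. HOXD10 had means of 5.01 in HUVEC, 6.63 in HSaVEC, 4.99 in HAoEC and 4.68 in HCoEC, and HOXD8 had 7.32 in both HUVEC and HAoEC, 7.86 in HSaVEC and 6.52 in HCoEC. The other regional transcription factors had a mean of 0.093, with MEIS2 called, and with the block also TBX1 (0.79) and TBX18 (0.72) higher and MEOX2 lower. In the axon guidance list (mean 0.12) SLIT2 and PLXNA1 (0.55) were higher and SEMA3A (-2.03) lower with the block. In the TGF-beta and BMP list (0.071) SMAD9 (-0.42) was lower, and in the inflammatory list (-0.12) TNFSF15. Fibroblast markers had a mean of 0.73, with FAP (2.36) the only member called when adjusted over the list alone. They differed by 1.14, 0.73 and 0.33 in numbers 1, 2 and 3. Smooth muscle and pericyte markers had a mean of 0.22 and cell cycle genes 0.18. Neither these nor the fibroblast, HOX and regional lists, called by camera at its preset correlation, were called with an estimated correlation. With the block and adjusted over the list alone, 8 HOX genes (7 lower, 1 higher), 5 regional factors, 6 axon guidance genes, 4 interferon genes, 2 inflammatory genes, the mesothelial and epithelial markers KRT8 and KRT18, HEY2 in the Notch list and SMAD9 were called. The haemostasis list (-0.35) was called only without the block at the preset correlation. Camera did not call, in either fit, the Notch (0.15), pan-endothelial (-0.018), interferon (0.086), shear stress (0.043) and cholesterol (-0.11) lists, the values being mean differences. Nor did it call the blood cell (0.012, camera direction down without the block) and mesothelial and epithelial (0.033, camera direction down in both fits) lists. The basement membrane (0.050, camera direction down with the block) and hypoxia (-0.0049, median 0.019) lists were not called either. In its mixed form and with the block, fry did call the Notch list (adjusted p = 0.0140) and the mesothelial and epithelial list (adjusted p = 0.00925).

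The 4 pairs of an artery with a vein shared CLDN11 and LAMA2 as genes called in 1 direction, and with number as a block also FAM174B and PLAC8. Limma with Benjamini-Hochberg adjustment called 3 genes for HAoEC against HUVEC, 22 for HAoEC against HSaVEC, 5 for HCoEC against HUVEC and 9 for HCoEC against HSaVEC. With the block these were 15, 79, 61 and 86. HAoEC and HSaVEC came from the same supplier, so supplier did not differ in that pair, while donor and lot were not named. Leaving out 1 array ended all calls without a block for HAoEC against HUVEC and HCoEC against HUVEC (without HUVEC 2), for HAoEC against HSaVEC (without HSaVEC 2 or HAoEC 1) and for HCoEC against HSaVEC (without HSaVEC 2 or HCoEC 2). The count of 22 was 2 without HSaVEC 1, 3 without HAoEC 2 and 5 without HSaVEC 3 or HAoEC 3. The count of 2 shared by all 4 pairs was 0 without HUVEC 2, HSaVEC 2, HAoEC 1, HAoEC 2 or HCoEC 2. In HAoEC against HUVEC the genes were LAMA2 (3.11), CLDN11 (-4.39) and NNAT, named after their values were seen. Pairing the vessels across kinds also called genes once number was a block. HAoEC and HUVEC against HCoEC and HSaVEC gave 0 genes without the block (378 at an unadjusted p under 0.05) and 45 with it. HAoEC and HSaVEC against HCoEC and HUVEC, where the first pair shares a supplier, gave 0 (237 at an unadjusted p under 0.05) and 16.

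Between coronary and aortic cells no gene was called without a block, and 2 were called with number as a block. With number as a block, ANKRD6 was 2.13-fold lower in HCoEC (-1.09, SE 0.10; limma, Benjamini-Hochberg adjusted p = 0.0283), and ABCA4, a lipid transporter of the ABC family, was 1.90-fold lower (-0.92, SE 0.10; limma, Benjamini-Hochberg adjusted p = 0.0428). HOX genes were the list with the most members past the threshold when adjusted over the list alone, all lower in HCoEC: HOXB6 (-1.45), HOXB7, HOXD1 (-1.11) and HOXD3 (-0.95), and with the block also HOXB5 (-0.73), HOXB9 (-0.68) and HOXD8 (-0.80). HOXB5 had a mean of 4.92 in HCoEC, within the range of the filter level, so the size of its difference is uncertain. Limma called 0 genes without the block, 249 had an unadjusted p under 0.05, and the lowest adjusted p was 0.952; with the block 1433 had an unadjusted p under 0.05. The count of 2 was 0 when any single HAoEC array, HUVEC 1, HSaVEC 1, HCoEC 1 or HCoEC 2 was left out, 8 without HCoEC 3, 0 in a test against a fold of 1.2, and 0 with number 3 against 1 and 2 as the block, and 7 of 100 permutations of the vessel labels within each number gave a count as large. In numbers 1, 2 and 3 ANKRD6 differed by -1.05, -1.14 and -1.08.

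Cell cycle genes had a mean of 0.50 in HCoEC minus HAoEC (0.22, 0.57 and 0.71 in numbers 1, 2 and 3), and HOX genes -0.46 (-0.33, -0.76 and -0.28). Camera at the preset correlation called both with adjusted p = 4.60e-16 and 8.14e-11, and neither with an estimated correlation (adjusted p = 0.384 for both). Arterial, inflammatory, interferon and basement membrane lists were called lower and smooth muscle and fibroblast lists higher at the preset correlation, and 0 of the 21 lists were called with an estimated one. With number as a block the smooth muscle (adjusted p = 0.181) and fibroblast (adjusted p = 0.192) lists were no longer called at the preset correlation. None of these 6 lists kept its sign across numbers 1, 2 and 3. Interferon genes differed by -0.92, -0.84 and 0.70, fibroblast markers by 1.34, 0.82 and -0.43, arterial markers by -0.043, 0.18 and -0.72, inflammatory genes by -0.43, -0.51 and 0.053, basement membrane genes by -0.012, 0.20 and -0.52, and smooth muscle markers by 0.41, 0.88 and -0.10.

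**Figure D4:**
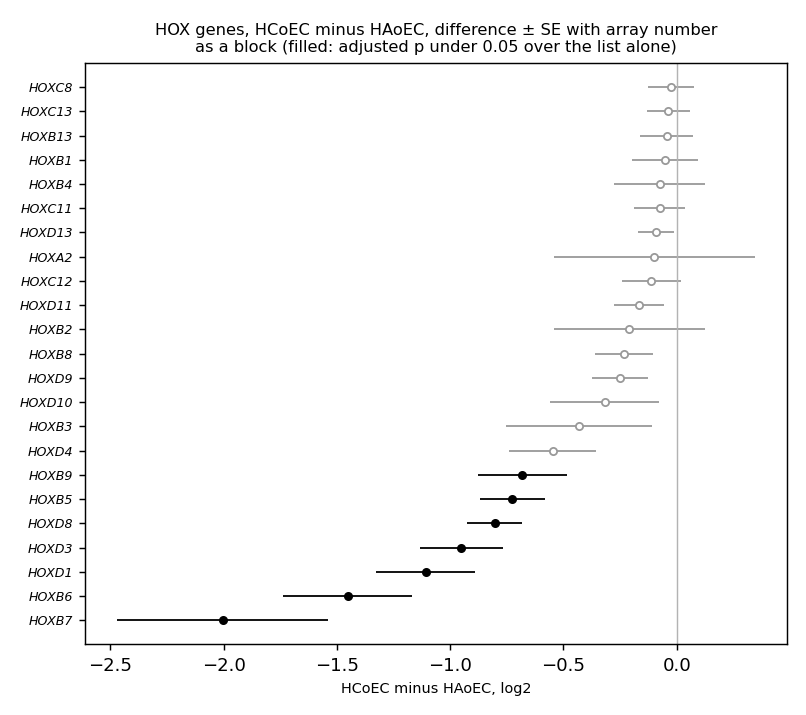
HCoEC minus HAoEC log2 difference (x axis) of each tested HOX gene with the standard error from the fit with array number as a block; filled symbols have an adjusted p under 0.05 over the list alone. The filled genes, all lower in HCoEC, are HOXB5, HOXB6, HOXB7, HOXB9, HOXD1, HOXD3 and HOXD8.

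Saphenous vein cells had more of the steroid dehydrogenase gene HSD17B2 than umbilical vein cells, and less of the transcription factor gene GATA3. HSD17B2 was 8.19-fold higher (3.03, SE 0.34, n = 3 and 3; limma, Benjamini-Hochberg adjusted p = 0.0114), from 5.30 ± 0.66 (SD, n = 3) in HUVEC to 8.33 ± 0.40 in HSaVEC. GATA3 was 5.60-fold lower (SE 0.28, limma, Benjamini-Hochberg adjusted p = 0.0114), with a mean of 8.48 ± 0.067 (SD, n = 3) in HUVEC. POF1B (2.87), SDR42E1 (2.38), GREB1L (1.93), ARHGAP25 (1.73) and the mannose receptor MRC1 (1.63) were higher in HSaVEC, and the homeobox gene MEIS1 (-2.17) and the planar polarity gene PRICKLE2 (-1.43) lower. These were the 9 genes called (331 at an unadjusted p under 0.05), none with overlap between 3 and 3 arrays, which chance alone gives to 10% of genes. POF1B, SDR42E1, GREB1L and MRC1, and VAV3 of the genes given next, lay at or under the filter level on all 3 HUVEC arrays, so the size of their differences is uncertain. Without HUVEC 1 or HSaVEC 2 the count was 0, without HUVEC 2 it was 1, a gene outside the 9, and without HUVEC 3 it was 14. With number as a block 59 were called, 35 higher and 24 lower in HSaVEC, including all 9, and the count ran from 20 to 81 when 1 array was left out. Higher with the block were the mechanosensitive channel PIEZO2 (2.97), CYTL1 (2.76), AGMO (2.55), ACSL5 (2.34), the growth factor HGF (2.27), the fatty acid binding protein FABP4 (2.19), VAV3 (2.07) and GMFG (1.97). Lower were the interferon-induced genes BST2 (-3.11) and IFITM1 (-2.86), SLIT2 (-2.75), the Wnt agonist RSPO3 (-2.65), MRAP2 (-2.46), the tropomyosin TPM2 (-2.25), RANBP17 (-2.13), KCNJ2 (-1.76), ERBB2 (-1.68) and SCN8A. Within numbers 1, 2 and 3 HSD17B2 differed by 3.03, 3.49 and 2.58, and BST2 by -3.83, -2.47 and -3.04.

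**Figure D5:**
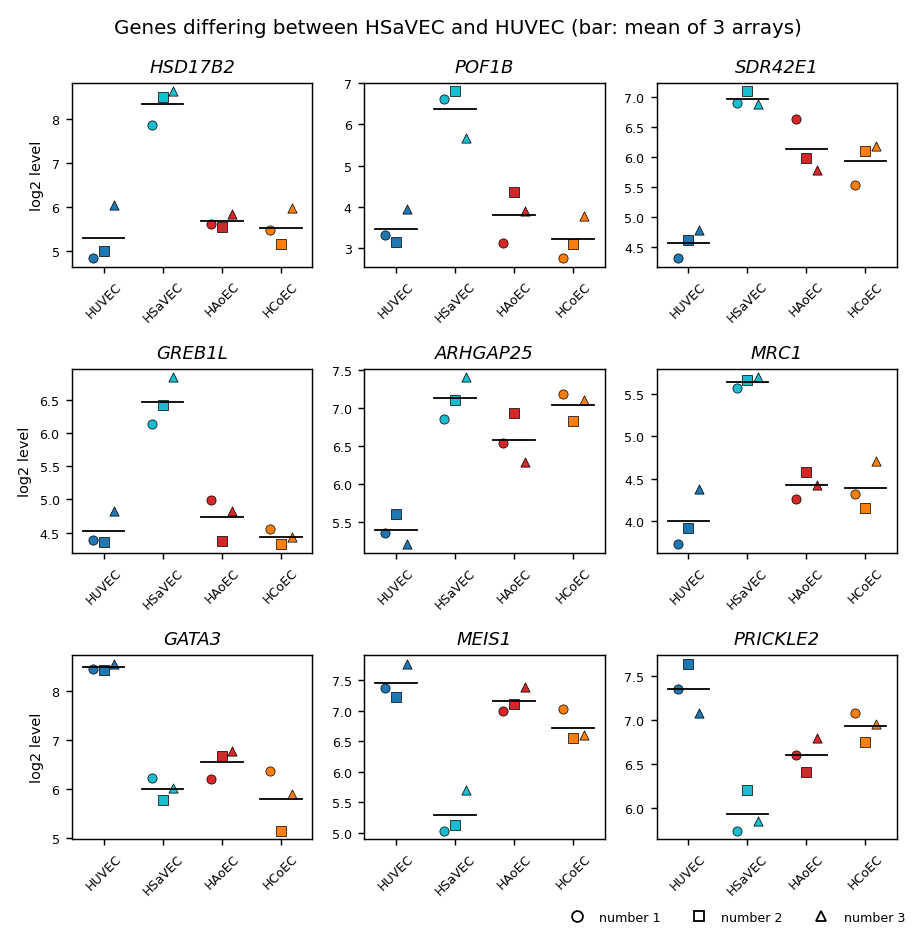
Log2 level (y axis) on each array of the 9 genes called for HSaVEC against HUVEC, by vessel of origin; points are arrays and bars are means of 3. HSD17B2 has a mean of 8.33 in HSaVEC and 5.30 in HUVEC.

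Among lists for the veins, lymphatic markers had a mean of 0.54 in HSaVEC minus HUVEC, with TFF3 (1.68) called with number as a block, and shear stress genes 0.30, with PGF (0.86) called with the block. Interferon genes had a mean of -0.54, but 0.057, -0.20 and -1.48 in numbers 1, 2 and 3. Camera at the preset correlation also called the cell cycle and cholesterol lists higher, with means of 0.21 and 0.19, and the inflammatory, regional and axon guidance lists lower. With number as a block the inflammatory and axon guidance lists (adjusted p = 0.160 for both) were no longer called. None of the 21 lists was called with an estimated correlation. Cell cycle genes differed by -0.46, 0.89 and 0.19 in the 3 numbers, cholesterol genes by -0.44, 0.15 and 0.85, and inflammatory genes by -0.19, 0.10 and -0.72, so like the interferon list these did not keep their sign within numbers.

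HSaVEC was the vessel with the most genes set apart from each of the other 3. HSD17B2, POF1B and GREB1L were higher there without a block, by at least 1.73 for GREB1L. That count of 3 was 0 when HUVEC 1, HSaVEC 1, HSaVEC 2, HCoEC 2 or any single HAoEC array was left out, and 1 without HUVEC 2 or HSaVEC 3. In the fit with number as a block 23 genes were set apart, 13 higher and 10 lower. AGMO (2.55), HGF (2.27) and VAV3 (2.07) were among the higher ones and SLIT2 (-2.75), TPM2 (-2.20) and ERBB2 (-1.68) among the lower, each value being the smallest of the 3 differences. POF1B and VAV3 lay at or under the filter level on all 9 arrays of the other vessels, and AGMO, HGF and GREB1L on most of them, which leaves the size of these differences uncertain. In HUVEC, 0 genes were set apart without the block and 3 with it: GATA3 higher, and CYTL1 (-2.75) and TMEM171 (-0.99) lower. In HCoEC, 0 were set apart without the block and ANKRD6 (-0.85) with it. In HAoEC limma called 0 in both fits.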

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

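The tests of a loss of endothelial cells and of a signal shared with other HOX clusters were chosen after the result was seen, as were the use of number as a block for the genes listed here and, for counts other than arteries against veins, the permutations within each number. Groups of 3 arrays are too small for a test of single outlying samples, so no gene here was singled out that way. The genes for the veins were called for arteries against veins in the fit with array number as a block. Their difference between the 2 veins also passed its own test in that fit. Genes of the kinds not named, such as HLA genes and antisense or non-coding symbols, were left out of the genes for the veins. The genes for the arteries were those whose difference between the 2 arteries passed its own test.

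In HSaVEC minus HUVEC, the log2 differences were 2.55 for AGMO, 0.87 for CUBN, 2.76 for CYTL1, 1.36 for DNAJC12, 1.80 for FOXP2, 1.93 for GREB1L, 2.27 for HGF, 1.62 for HOXD10, 3.03 for HSD17B2, 1.68 for TFF3, 0.99 for TMEM171 and 2.07 for VAV3. They were -2.48 for GATA3, -0.70 for IFI27L2, -0.90 for MEIS2, -2.75 for SLIT2 and -1.33 for TBX18. In HCoEC minus HAoEC they were -0.92 for ABCA4 and -1.09 for ANKRD6. Each vessel's cells had a single commercial source, so vessel, donor and supplier cannot be separated for them.

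The 4 arrays numbered 3 stood apart from the other 8. Array scaling alone was argued against: after quantile normalization number 3 against 1 and 2 still explained 53.1% of the variance, and vessel 23.7%. A background that depends on signal stayed open, since, with genes parted by mean level into 4 equal sets, the shift of the lowest set exceeded that of the highest by 0.15, between the bounds set beforehand. A different growth state stayed open as well. After quantile normalization the cell cycle list was shifted by a median of 0.27, outside the range of -0.22 to 0.24 of random lists. Those lists were matched on level but not on the correlation between genes, estimated at 0.76 for the cell cycle list without a block. They therefore cannot decide this. The labels give no group for the numbers, so processing and culture remained open together.

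Some lymphatic marker genes were higher in HSaVEC than in the arteries. LYVE1 was higher in HSaVEC than in the mean of the arteries by 4.01, PROX1 by 1.99, FLT4 by 1.86 and TFF3 by 1.71, whereas PDPN (-0.40, SE 0.38), CCL21 (-0.19, SE 0.14), RELN (-0.094, SE 0.66) and MMRN1 (0.10, SE 0.14) were not. In HUVEC against the arteries no marker passed the threshold, with 2.41 for LYVE1, 0.97 for PROX1, 1.17 for FLT4, 0.033 for TFF3 and -2.38 for RELN. Of PDPN, CCL21, RELN and MMRN1, 0 were lower in HSaVEC than in the arteries by more than 2 standard errors. PDPN had means of 4.90 in HSaVEC, 4.93 in HAoEC and 5.67 in HCoEC, and CCL21 had 5.29, 5.53 and 5.44. These lie within or just above the range of the filter level, so both genes could hardly be lower in HSaVEC. RELN (7.75, 8.06 and 7.63 in the same order) and MMRN1 (12.25, 12.21 and 12.09) lay well above it. An admixture of lymphatic cells could therefore neither be excluded nor supported by this test. Venous origin of the cells stays open as an untested biological explanation.

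Some HOXB genes were lower in HCoEC than in the mean of the other vessels: HOXB5 (-0.80) and HOXB6 (-1.48) passed the threshold, HOXB7 (-2.24), HOXB8 (-0.29) and HOXB9 (-0.79) did not, and HOXB1 to HOXB4 and HOXB13 lay between -0.24 and 0.024. HOXB5 had a mean of 4.92 in HCoEC, within the range of the filter level, so the size of its difference is uncertain. The median over HOXB5 to HOXB9, a set chosen from the data, was -0.80. A single array was argued against, since the median ran from -0.98 to -0.69 when each HCoEC array was left out. A loss of endothelial cells was argued against too, with a pan-endothelial median of -0.0072 (SE 0.041 from resampling the genes of the list). The 3 tested HOXC and HOXD genes numbered 8 and 9 had a median of -0.51 (SE 0.32 by the same resampling). These SEs measure the spread between genes of a list and not between arrays. HOXD8 fell by 0.99 and passed the threshold and HOXC8 was at -0.087, so the change was not confined to HOXB. Its extent in other clusters stayed open, and HOXA2 was the only HOXA gene tested. Position of the coronary artery in the body, donor and supplier remain untested as candidate explanations.

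Other groupings of the same arrays were fitted to see whether chance gives counts as large. For arteries against veins 4 of 100 groupings reached the real count of 13, and the highest of the others was 7892. The groupings were drawn without regard to array number, whereas each real vessel holds 1 array of each number. Number 3 against 1 and 2 explained 66.5% of the variance as deposited, so drawn groups can also differ by number. Which arrays the grouping with 7892 put together was not examined. Such draws are not like the real grouping, so the shares given here cannot exclude chance. For genes called in all 4 pairs the real count of 2 was reached by 1 of 100 groupings (highest other 1), and for genes set apart in HSaVEC the real count of 3 by 1 of 100 (highest other 1). A real count of 0 is matched by all 100 groupings by construction, which says nothing about chance. This holds for the other pairings of vessels (highest others 8062 and 7788) and for genes set apart in HUVEC (2), HAoEC (1) and HCoEC (2843). For the 6 comparisons of 2 vessels there are 10 splits, too few for a share under 0.05. The real counts and the highest others were 0 and 0 for HCoEC against HAoEC (reached by 10), 9 and 0 for HSaVEC against HUVEC, 3 and 0 for HAoEC against HUVEC, 22 and 0 for HAoEC against HSaVEC, 5 and 0 for HCoEC against HUVEC, and 9 and 1 for HCoEC against HSaVEC.

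With number as a block, vessel labels were instead permuted within each number, 100 arrangements with the real one. Only 1 of 100, the real one, reached 103 for arteries against veins (highest other 7), and the same held for the other pairings of vessels, with 45 (highest other 10) and 16 (highest other 5). Counts this large were therefore rare when all 4 vessels were exchanged, and this was not particular to arteries against veins. Only the real arrangement, 1 of 100, also reached the counts for HSaVEC against HUVEC (59, highest other 32) and HAoEC against HSaVEC (79, highest other 22). The same held for HCoEC against HUVEC (61, highest other 30) and HCoEC against HSaVEC (86, highest other 17). It held too for all 4 pairs (4, highest other 0) and genes set apart in HSaVEC (23, highest other 1). The permutations exchanged all 4 vessels within a number, so for 2 vessels they do not test that pair alone and cannot exclude chance for it. For HAoEC against HUVEC 4 of 100 reached 15 (highest other 35), and for genes set apart in HUVEC 3 of 100 reached 3 (highest other 13). Chance was not excluded for HCoEC against HAoEC, where 7 of 100 reached 2 (highest other 44), or for genes set apart in HCoEC, where 5 of 100 reached 1 (highest other 8).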

How the results depend on the processing

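The fits without the 4 arrays numbered 3, with number 3 against 1 and 2 as a block, with replicate block and quantile normalization together, with vessel as a random block beside the number, and all alternatives within the fit with the replicate block were chosen after the data were seen. No depth applies to arrays, and weak signals near background limit what could be called. The arterial, venous and lymphatic lists, arteries against veins, kept their direction and their camera call (preset correlation) under every alternative run, with means of 0.50 to 0.68, -0.48 to -0.35 and -0.70 to -0.41 without a block. These alternatives used camera only at the preset correlation. At an estimated correlation with number as a block, camera called none of these lists (adjusted p = 0.24, 0.256 and 0.24). Over all alternatives, named genes kept direction and call in 1151 cases and lost the call in 509, with 0 reversed. Named genes had been chosen as called and without overlap between the compared arrays, so a reversal was hardly possible and is no test. Genes named in both fits are counted in each. Lists, most of them not called to begin with, kept their direction and their side of the threshold in 2517 cases. They lost the call in 105, gained it in 73 and reversed in 14. The counts of genes were less stable: no filter, a trended robust prior and the mean of all probe sets left every count without a block within 1.5 times, and the other settings moved some. Where no reason is given, the cause was not tested. Counts below are in the order arteries against veins, HCoEC against HAoEC, HSaVEC against HUVEC, HAoEC against HUVEC, HAoEC against HSaVEC, HCoEC against HUVEC, HCoEC against HSaVEC, the pairings HAoEC and HUVEC, and HAoEC and HSaVEC, against the rest, all 4 pairs, and genes set apart in HUVEC, HSaVEC, HAoEC and HCoEC. As reported they were 13, 0, 9, 3, 22, 5, 9, 0, 0, 2, 0, 3, 0 and 0.

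With the replicate block they were 103, 2, 59, 15, 79, 61, 86, 45, 16, 4, 3, 23, 0 and 1, the block removing the spread between numbers. With number 3 against 1 and 2 as a block they were 128, 0, 78, 20, 106, 67, 110, 63, 23, 3, 5, 27, 0 and 0, and with replicate block and quantile normalization 89, 1, 59, 18, 78, 51, 82, 24, 20, 3, 3, 21, 0 and 1. Without the 4 arrays numbered 3 they were 62, 9, 62, 15, 35, 64, 69, 31, 15, 2, 8, 17, 0 and 8, and with array weights 384, 128, 694, 169, 384, 389, 415, 559, 245, 20, 51, 100, 13 and 45. The estimated weights were 0.124 to 0.159 for the arrays numbered 3 and 1.28 to 7.17 for the others. The counts with array weights therefore rest mainly on the arrays numbered 1 and 2.

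Quantile normalization gave 22 for arteries against veins, 21 for HSaVEC against HUVEC, 15 for HCoEC against HSaVEC, 6 and 2 for the pairings and 8 set apart in HSaVEC. Median centring gave 23, 19 and 23 for these comparisons, 35 for HAoEC against HSaVEC, 5 and 3 for the pairings and 8 set apart in HSaVEC. The filter at the 50th percentile gave 13 for HAoEC against HSaVEC, 3 for HCoEC against HSaVEC, 1 for all 4 pairs and 1 set apart in HSaVEC. The test against a fold of 1.2 gave 12 for HAoEC against HSaVEC and 1 for all 4 pairs. The unmoderated statistic gave 2 for arteries against veins and 0 for every other count. With only the 6 arrays compared, fewer samples, the counts were 3 for HSaVEC against HUVEC, 0 for HAoEC against HUVEC, 0 for HCoEC against HUVEC and 2 for HCoEC against HSaVEC. For arteries against veins, vessel as a random block gave 129 with a correlation of -0.310, which treats arrays of 1 vessel as less alike than others, 2 groups ignoring vessel gave 5, and vessel as a random block with the replicate block gave 4.

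Within the fit with the replicate block, arteries against veins had 27 genes against a fold of 1.2, 7 with the unmoderated statistic and 49 without the 4 arrays numbered 3. HCoEC against HAoEC had 17 with array weights, 1 with the filter at the 50th percentile, 1 with quantile normalization, 0 against a fold of 1.2, 0 with the unmoderated statistic and 6 without the arrays numbered 3. HSaVEC against HUVEC had 31, 0 and 35 against a fold of 1.2, with the unmoderated statistic and without those arrays.

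With 1 array left out the counts ran from 2 to 19, 0 to 2, 0 to 14, 0 to 7, 0 to 24, 0 to 13, 0 to 13, 0 to 4, 0 to 1, 0 to 3, 0 to 3, 0 to 3, 0 to 0 and 0 to 2, in the order given. For arteries against veins the count fell to 2 without HSaVEC 1, HCoEC 1 or HCoEC 2, 3 without HUVEC 1, 4 without HAoEC 1, 8 without HUVEC 2, and 7 without HSaVEC 2 or HSaVEC 3. For HSaVEC against HUVEC it was 0 without HUVEC 1 or HSaVEC 2, 1 without HUVEC 2 and 14 without HUVEC 3. With the replicate block the ranges were 33 to 100 for arteries against veins, 0 to 8 for HCoEC against HAoEC and 20 to 81 for HSaVEC against HUVEC. For arteries against veins it was 33 without HAoEC 3, 43 without HSaVEC 1, 46 without HCoEC 2, 49 without HAoEC 1, 52 without HSaVEC 3, 57 without HUVEC 2 or HCoEC 1 and 59 without HUVEC 1. For HCoEC against HAoEC it was 0 without any single HAoEC array, HUVEC 1, HSaVEC 1, HCoEC 1 or HCoEC 2, 1 without HUVEC 3, 4 without HSaVEC 3 and 8 without HCoEC 3. For HSaVEC against HUVEC it was 20, 37 and 29 without HSaVEC 1, 2 and 3, and 23 and 29 without HUVEC 1 and 2.

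For some lists the direction given by camera reversed, which can differ from the sign of the mean. For HSaVEC against HUVEC the interferon list was 0.0013 and the cholesterol list -0.12 with array weights, and -0.073 and -0.14 without the 4 arrays numbered 3. With 1 array left out the cholesterol list ran from -0.22 (without HSaVEC 3) to 0.45, and with the replicate block from -0.035 to 0.40, and the cell cycle list with the replicate block from -0.035 (without HSaVEC 2) to 0.46. For HCoEC against HAoEC the ranges were -0.35 to 0.0096 for the arterial list, -0.10 to 0.17 for the venous list, -0.043 to 0.097 for the pan-endothelial list and -0.30 to 0.057 for the basement membrane list. The cause was not tested.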

Other observations

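The arrays numbered 3 differed from the others in several gene lists after quantile normalization. Venous markers had a median shift of -0.75 (random lists -0.29 to 0.31), fibroblast markers -0.55 (-0.30 to 0.32), arterial markers -0.32 (-0.20 to 0.25) and pan-endothelial markers -0.24 (-0.24 to 0.29). The hypoxia list was shifted by 0.24, within its range of -0.23 to 0.27. The random lists were matched on level but not on the correlation between genes of a list, so these ranges do not test the shifts. Before normalization the median shift of genes was 0.61, 0.49, 0.49 and 0.47 in 4 equal sets of genes from the lowest to the highest mean level.

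HOXD10 was higher in HSaVEC than in the mean of the other vessels by 1.74 (limma with number as a block, Benjamini-Hochberg adjusted p = 0.00435), HOXD8 by 0.81 and HOXD9 by 0.68. These values were looked at after the HOX list had been tested.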
